A study of Vibrio natriegens NBRC 15636 = ATCC 14048 = DSM 759 with 6 samples.

How the data were processed

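RNA was sequenced from 6 samples of Vibrio natriegens, a fast-growing marine bacterium that can fix nitrogen. The samples came from 3 strains with 2 libraries each. The parent carries a kanamycin marker in place of dns, a nuclease gene, and the other strains lack ntrB and ntrC, or nifA, in that background. Per the labels' protocols, suspensions of cells that were not growing were held for 2 h at 30 °C with shaking at 150 rpm, under argon and in a medium with no source of nitrogen. RNA was taken up in TRIzol and chloroform and treated with DNase. Ribosomal RNA was depleted, and stranded total RNA libraries were made with an Illumina kit, per the labels' protocols.

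The deposited files give 1 FPKM value (fragments per kilobase of gene, scaled to the fragments of the library) for each gene identifier and library, per the file headers. The submitters' processing notes name Trim Galore 0.6.6, cutadapt 1.18, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.15.1 and StringTie 1.3.3b. Their settings and the genome build are not given in the sources used here, so no coordinates are reported. FPKM is scaled to each library's total, so the loss of abundant transcripts alone raises the FPKM of all other genes. The design fixed before the data were examined assumed TPM. The deposited files hold FPKM, so the planned log-scale test was applied to FPKM.

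All 1490 identifiers matched a RefSeq gene table of assembly ASM145625v1, which gave symbols, gene types, lengths and neighbours. The table holds 4504 protein-coding genes, of which 1322 are listed in the files used here, so every count refers to a part of the genome. It gives no products and no strand. In 77 cases an identifier stood on more than 1 row in a library, and each of these 77 has a symbol shared by several loci. Which row belongs to which locus is not given. For 73 of them the rows were summed, and the summed value is uncertain as a measure of any 1 locus. Of the genes named in the results, adhE, aspA, groL, hisC, modA, modB, modC, nirD, nqrM, putA, putP, rsxA, rsxC and soxR are such sums. The other 4 had different numbers of rows in different libraries and were left out. Genes for rRNA (34 identifiers) and tRNA (129) were left out as well, which left 1323 genes.

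FPKM was rescaled by a median-of-ratios factor per library, taken over genes with a mean FPKM of at least 10. This sets the median gene to no change and so assumes that most genes did not move. The factors were 0.688 and 0.728 in the parent, 1.34 and 1.41 in the ntrBC deletion, and 1.02 and 1.03 in the nifA deletion. Genes with a mean of at least 5 were tested, 1197 in all, on log2(rescaled FPKM + 1). The pseudocount of 1 understates the change of genes with low values. Levels are means of rescaled FPKM ± SD of 2 libraries, and a stated fold is the ratio of these means.

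The 3 strains entered 1 limma fit (limma 3.58.1, R 4.3.3, eBayes with a trend) with no replicate block. It had 3 residual and 7.09 prior degrees of freedom. In all, 3 contrasts were tested, 2-sided: each deletion against the parent, and the nifA against the ntrBC deletion. Calls are at a Benjamini-Hochberg adjusted p under 0.05. An exact permutation test of 2 against 2 libraries cannot go below a p of 0.333. The labels do not say that the libraries of a strain came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Across genes, the log2 values of both libraries of a strain had a Pearson r of 0.997, 0.996 and 0.996 in the parent, the ntrBC deletion and the nifA deletion, where genes are not independent replicates.

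For 17 gene lists named before the data were examined, members called higher and lower were counted after adjustment over all genes and adjusted over the list alone. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation, under which no list was called in any comparison. The lists covered nitrogenase, nitrogen assimilation and scavenging, molybdenum and iron supply, the Rnf electron transfer complex and flavodoxin, ribosomal proteins, ATP synthase, the stringent response and ribosome hibernation, amino acid biosynthesis, flagella and chemotaxis, type VI secretion, quorum sensing, phage shock and envelope stress, heat shock and chaperones, oxidative stress, anaerobic respiration and fermentation, carbon storage, and peptide and amino acid transport. Membership by product had been planned for some lists. Since only symbols were at hand, patterns of symbols written after the data were seen took its place for 6 lists. This changed the tested members of the flagellar list (31 in place of 1) and the ribosomal protein list (54 in place of 0) and of no other list, so the p-values of these lists rest on memberships set after the data were seen. Of the type VI secretion list, 1 gene was listed and 0 were tested.

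The genes to be named were set by a rule. It takes the deleted genes, nifH, nifD, nifK, nifB, nifL, glnA and glnB in every comparison. It adds the 10 higher and 10 lower called genes with the largest log2 change, among those with a mean of at least 20 in the higher strain and no overlap between libraries. Lastly it adds up to 4 called members with the smallest p of each list that was called or had at least 3 called members. The rule also names dns, nifJ, glnK, amtB and rpoN, which are not analysed here. Genes outside the rule are said to be so where they appear.

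The fit was tested on simulated data built on the comparison of the ntrBC deletion with the parent, with 200 of 1197 genes changed in each of 20 runs. It recovered 93.7% of genes changed by a log2 of 0.5, 99.3% at 1, 98.7% at 2 and 97.9% at 4, and 4.77% of its calls were false. The simulation left most genes unchanged, whereas 609 genes were called in the ntrBC deletion. It does not test the rescaling for the case that most genes moved, so these rates may not hold for the data. Of 320 unchanged simulated lists, 5.31% had a p under 0.05. Genes were drawn independently of each other there, so this does not test the preset correlation on which the list tests rest.

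The depth of the libraries is unknown. To look for the value of 1 fragment, the 100 lowest values above 0 of each library were multiplied by gene length and compared with multiples of a common step. At most 19.7 to 24.4% lay within 0.05 of a whole multiple, against 21.2 to 22.0% after random shifts, so no counts were recovered and no counting interval is given.

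Alternatives covered the pseudocount, the filter, 2 other scalings, rRNA and tRNA genes kept, the replicate block, the prior of the fit, fits of 2 strains alone, a size threshold and each library left out in turn. Fits without repeated identifiers, lists without the deleted genes and lists of symbols fixed before alone were added after the data were seen.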

Results

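Transcript levels were measured by RNA sequencing in nitrogen-starved cells of 3 Vibrio natriegens strains, with 2 libraries per strain. The study asked how this species controls nitrogenase, the enzyme that reduces nitrogen gas to ammonia, in comparison with related bacteria. The parent was set beside a strain without ntrB and ntrC, the sensor kinase and response regulator of the nitrogen starvation response, and a strain without nifA, the activator of nitrogenase genes. These are called the ntrBC deletion and the nifA deletion. The deposited FPKM values summed to 873987 and 832930 in the parent, 1009150 and 977715 in the ntrBC deletion, and 883009 and 869098 in the nifA deletion. Depth in reads is unknown.

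By FPKM multiplied by gene length, the listed genes held between 45.8% and 53.1% of each library's fragments. In the parent, 12 nif genes alone held 10.9% and 11.5%. In the ntrBC deletion they held 0.00681% and 0.00604%, and in the nifA deletion 0.435% and 0.381%. The stable RNA ssrA, which frees stalled ribosomes, held 20.6% and 18.7% in the parent, 26.5% and 25.1% in the ntrBC deletion, and 22.0% and 21.9% in the nifA deletion. As deposited, the median log2 change of all tested genes was 0.92 in the ntrBC deletion and 0.52 in the nifA deletion. All changes below are relative to that shift, after rescaling, unless FPKM as deposited is named. As deposited, 1017 of 1198 tested genes were called higher in the ntrBC deletion and 970 in the nifA deletion. Counts of higher list members as deposited are to be read against these.

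The deleted genes were listed at 0 or far below the parent in the strains named for them. Under the symbol glnL, ntrB had a deposited FPKM of 869 and 871 in the parent and 768 and 824 in the nifA deletion, and was listed at 0 in both libraries of the ntrBC deletion. Under the symbol glnG, ntrC was at 531 and 536 in the parent, at 441 and 420 in the nifA deletion, and also listed at 0 in both libraries of the ntrBC deletion. The level of nifA was 2369 and 2288 in the parent and 102 and 88.8 in the nifA deletion, where 2.82% of the parent level remained after rescaling (4.09% as deposited). It was lower still in the ntrBC deletion, at 3.99 and 4.86, or 0.0974% of the parent after rescaling.

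**Figure D1:**
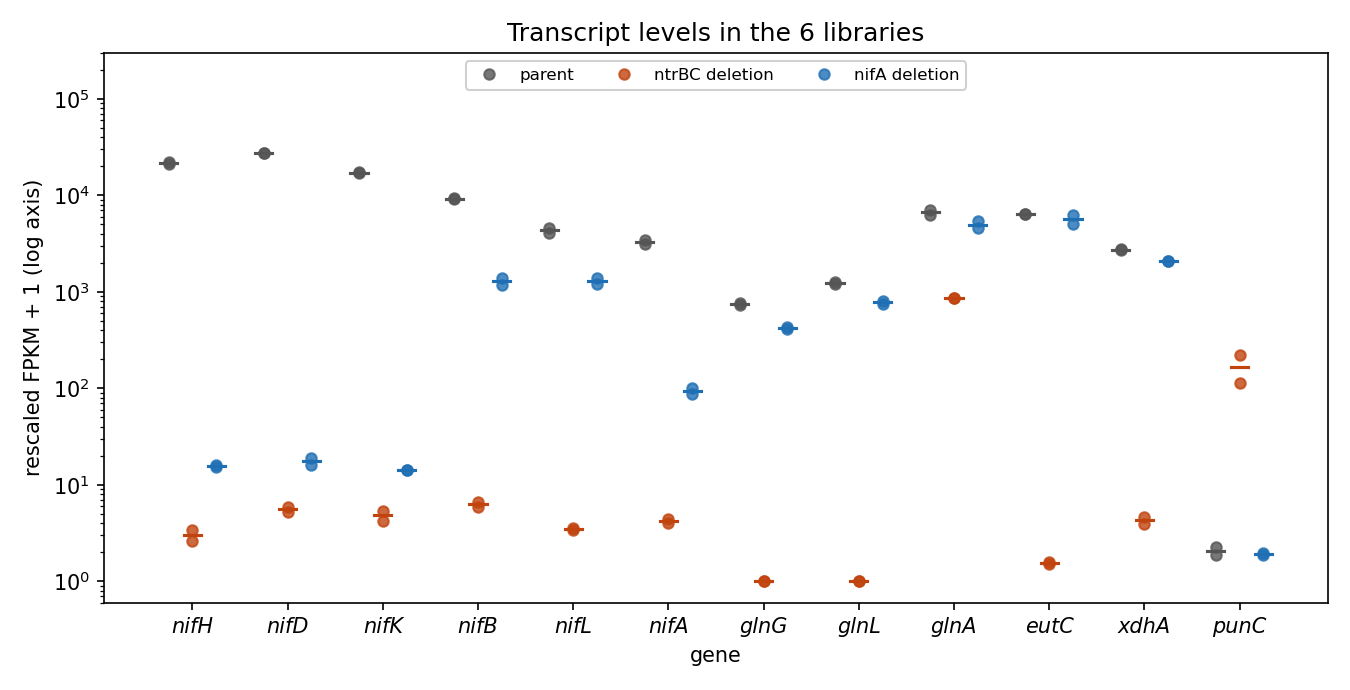
Rescaled FPKM + 1 on a log axis for 12 genes, with 1 dot per library, 2 libraries per strain, and a bar at their mean. In the ntrBC deletion nifH, nifB and nifL lay near the bottom of the axis, while in the nifA deletion nifB and nifL held means of 1281 and 1306 and eutC and xdhA means of 5657 and 2068.

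Loss of ntrBC was set against the parent to find what this regulator pair controls under nitrogen starvation. All 12 tested nitrogenase genes fell. Transcripts of nifH, which encodes the iron protein of nitrogenase, dropped from 21583 ± 656 to 2.00 ± 0.536 (SD, n = 2 each), 10800-fold lower. Those of nifD and nifK, for the subunits of the molybdenum-iron protein, were 6006-fold and 4507-fold lower. The regulatory genes nifL and nifA were 1750-fold and 1026-fold lower, and nifB, needed for the cofactor, 1758-fold lower. The list was called lower by limma camera with a Benjamini-Hochberg adjusted p = 2.69e-16 (adjusted p = 0.226 with an estimated correlation), 12 of 12 genes fell both over all genes and adjusted over the list alone, and all 12 also fell on FPKM as deposited.

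Genes for the capture of nitrogen fell with them. Glutamine synthetase, glnA, dropped from 6709 ± 527 to 866 ± 4.10 (SD, n = 2 each), with a log2 change of -2.95 ± 0.10 (SE) and a limma Benjamini-Hochberg adjusted p of 1.18e-09. The genes nirD, of nitrite reductase, and aspA, of aspartate ammonia-lyase, were 17.1-fold and 11.3-fold lower, each as a sum of rows of several loci that share a symbol. Outside the rule for named genes and chosen after their values were seen, the urease gene ureC fell from 263 to 27.6 and the urea transporter gene urtA from 2453 to 422. Of 21 tested members of the nitrogen assimilation and scavenging list, 17 fell and 2 rose, with the same counts when adjusted over the list alone, and the deleted glnL and glnG are among the 17. The list was called lower (limma camera, Benjamini-Hochberg adjusted p = 1.06e-08, or 1e-06 without the deleted genes; adjusted p = 0.386 with an estimated correlation), and on FPKM as deposited 17 members fell and 4 rose. The gene of the PII signal protein, glnB, did not pass the test after rescaling, at 64.5 ± 7.39 in the parent and 59.6 ± 2.67 in the ntrBC deletion (SD, n = 2 each; log2 -0.11, limma Benjamini-Hochberg adjusted p = 0.382). On FPKM as deposited glnB was called higher (log2 0.84, limma Benjamini-Hochberg adjusted p = 3.6e-06).

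The largest fall outside the nif genes was that of eutC, for the small subunit of ethanolamine ammonia-lyase, from 6440 ± 16.9 to 0.536 ± 0.0408 (SD, n = 2 each), 12020-fold lower. Beside it, eat, an ethanolamine permease gene, fell from 5876 ± 487 to 3.49 ± 0.340, 1685-fold lower. The molybdate transporter genes modA, modB and modC were 182-fold, 303-fold and 237-fold lower, and rsxA and rsxC, of an electron transfer complex also called Rnf, 141-fold and 127-fold lower. These mod and rsx values sum rows of several loci that share a symbol. Rows are ranked by size within each library, so a rank need not be the same locus in every strain. For modA, the larger row was at 3982 and 4047 deposited FPKM in the parent and at 37.4 and 38.8 in the ntrBC deletion. The smaller was at 16.8 and 18.5 in the parent and at 5.17 and 4.72 in the ntrBC deletion. Neither the molybdenum and iron supply list (6 higher and 9 lower of 19, limma camera Benjamini-Hochberg adjusted p = 0.311) nor the Rnf and flavodoxin list (1 higher and 3 lower of 10, adjusted p = 0.231) was called as a whole, and adjusted over the list alone the counts were 6 and 9, and 0 and 3. As deposited they turned to 13 higher and 3 lower, and 8 higher and 2 lower.

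The flagellar list, whose members were all but 1 taken by a pattern of symbols written after the data were seen, was mostly lower. The hook-filament junction genes flgK and flgL were 8.50-fold and 4.51-fold lower, flgJ 7.76-fold and flaG 4.43-fold, with flgK at 68.1 ± 1.42 in the parent and 8.01 ± 0.0269 in the ntrBC deletion (SD, n = 2 each). Of 31 tested flagellar and chemotaxis genes 29 fell and 1 rose, over all genes and adjusted over the list alone, whereas as deposited 19 fell and 3 rose. With limma camera the list was called lower (Benjamini-Hochberg adjusted p = 1.81e-11; adjusted p = 0.386 with an estimated correlation).

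More amino acid biosynthesis genes rose than fell. The histidine gene hisC, summed over such rows, was 2.86-fold higher, the arginine genes argH, argA and argC 2.79-fold, 2.67-fold and 2.56-fold, the serine gene serA 2.29-fold and the tryptophan gene trpA 1.91-fold. Of 58 tested members 34 rose and 9 fell (35 and 9 adjusted over the list alone). As deposited 57 rose and 0 fell, where 1017 of all 1198 genes tested rose. The list was called higher by limma camera (Benjamini-Hochberg adjusted p = 3.33e-05; adjusted p = 0.226 with an estimated correlation). Also higher were glmS, an amino sugar enzyme that uses glutamine (2.41-fold), and fadR, a regulator of fatty acid metabolism (2.47-fold).

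Fumarate reductase genes rose as well, frdD from 18.0 ± 4.48 to 73.9 ± 7.80 (SD, n = 2 each; 4.09-fold), frdC 3.52-fold and frdA 2.95-fold, together with adhE, an alcohol dehydrogenase gene (2.26-fold, summed over rows of several loci). The anaerobic respiration and fermentation list had 9 of 18 members higher and 1 lower, with the same counts adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.00704; adjusted p = 0.42 with an estimated correlation). On FPKM as deposited 17 members rose and the call of the list was lost (adjusted p = 0.131). Among 11 peptide and amino acid transporter genes 8 rose and 1 fell, likewise when adjusted over the list alone. They include the arginine transporter gene artQ, 1.98-fold higher, and the proline transporter gene putP, 9.76-fold lower as a sum of 3 rows. Its smallest row, by size in each library, was 2.83 and 3.09 deposited FPKM in the parent and 5.53 and 3.55 in the ntrBC deletion. These need not be values of the same locus. This list was called higher by limma camera (Benjamini-Hochberg adjusted p = 0.0327; adjusted p = 0.499 with an estimated correlation), and the call was lost as deposited (0.603) and without ntrBC deletion replicate 2 (0.0786).

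The largest rise was that of punC, a purine nucleoside transporter gene, from 1.06 ± 0.285 in the parent to 166 ± 75.5 in the ntrBC deletion (SD, n = 2 each), 157-fold higher (log2 6.27 ± 0.26 SE, limma Benjamini-Hochberg adjusted p = 7.21e-09). Its libraries stood at 113 and 220 in the ntrBC deletion and at no more than 1.26 in the others. The alkyl hydroperoxide reductase genes ahpC and ahpF were 9.85-fold and 7.24-fold lower, and phaC, the polyhydroxyalkanoate synthase gene, 3.96-fold lower.

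Other lists were not called by limma camera in this comparison (Benjamini-Hochberg adjusted p of each list follows its counts). Ribosomal protein genes had 8 higher and 23 lower of 54 (0.227), of which 9 and 23 adjusted over the list alone, and on FPKM as deposited this turned to 50 higher and 0 lower. Heat shock and chaperone genes had 3 higher and 8 lower of 15 (0.227), with groL (a sum of rows of several loci) and dnaK 2.34-fold and 2.12-fold lower, where dnaK no longer passed as deposited (log2 -0.12, adjusted p = 0.283), and phage shock and envelope stress genes 0 higher and 5 lower of 9 (0.227). As deposited these lists had 10 higher and 1 lower, and 7 higher and 1 lower. Oxidative stress genes had 2 higher and 4 lower of 9 (0.309), and stringent response and ribosome hibernation genes 2 higher and 5 lower of 10 (0.693), turning to 7 and 2, and 10 and 0, as deposited. For these 4 lists the counts adjusted over the list alone were the same. Quorum sensing genes had 2 higher and 0 lower of 5 (0.226), over all genes and adjusted over the list alone. Of 7 ATP synthase genes 2 were higher, but 0 adjusted over the list alone (0.226), and the list was called without ntrBC deletion replicate 2 (0.0479). As deposited all 5 quorum sensing and all 7 ATP synthase genes were higher. Of 6 carbon storage genes 1 was higher and 5 lower, likewise adjusted over the list alone (0.0602), with 2 and 2 as deposited, and the list was called without nifA deletion replicate 1 (0.0478) or 2 (0.0473).

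Across the 1197 tested genes, limma with Benjamini-Hochberg adjustment called 609 in the ntrBC deletion, 284 higher and 325 lower. At a log2 change of at least 1 there were 17 higher and 129 lower. On FPKM as deposited the calls were 1017 higher and 111 lower. In the same direction under both scalings, 284 genes were called higher and 111 lower, and 143 were called in opposite directions. The shift of the deposited values favours higher calls. Agreement among higher genes was therefore largely fixed in advance and is no separate support. With a log2 change of at least 1 under both, 17 were higher and 72 lower.

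**Figure D2:**
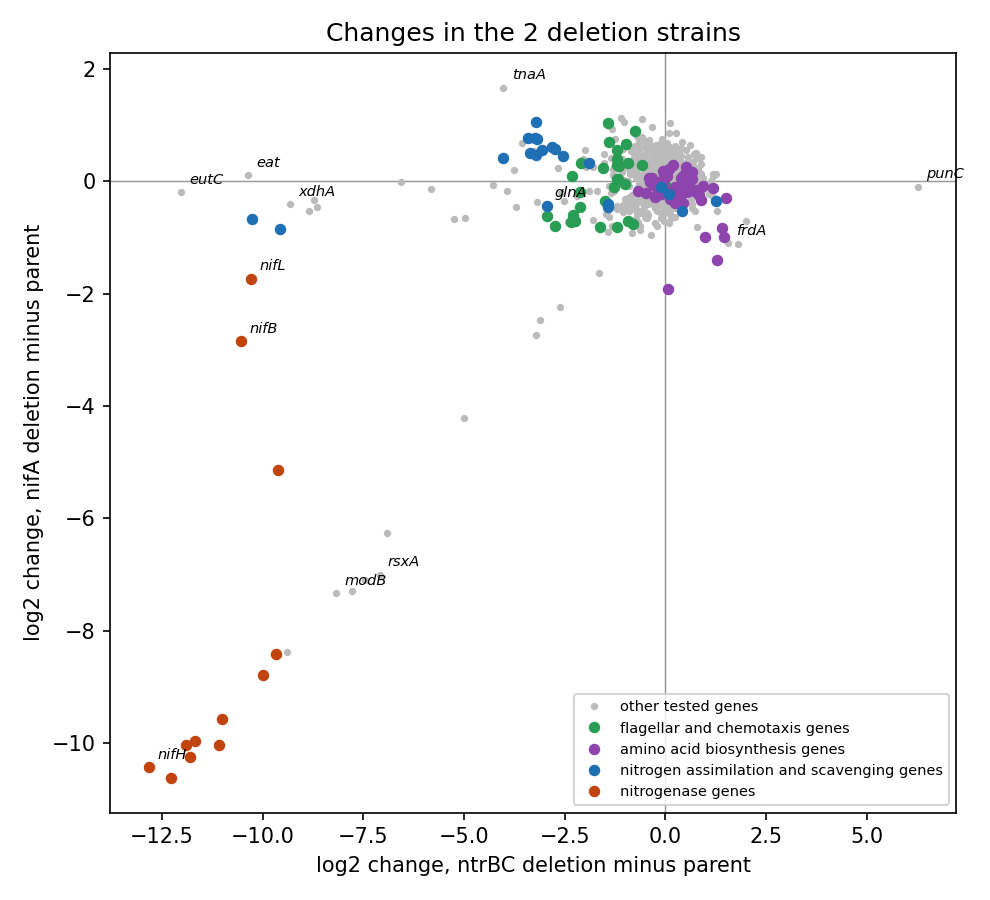
Log2 change in the ntrBC deletion (x axis) against that in the nifA deletion (y axis), each minus the parent on log2(rescaled FPKM + 1), with 1 dot per tested gene (1197) and 4 gene lists in colour. Most nitrogenase genes lie far to the lower left, nifB and nifL lie at -2.85 and -1.73 on the y axis, and eutC and eat lie at the far left near 0 on the y axis. On FPKM as deposited the median gene lies 0.92 further right and 0.52 further up, so that amino acid genes near 0 on the y axis turn from lower to higher in the nifA deletion.

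Loss of nifA was set against the parent to find what NifA controls. All 12 tested nitrogenase genes, the deleted nifA among them, fell here as well. Transcripts of nifH dropped to 14.6 ± 0.506 (SD, n = 2), 1480-fold below the parent, and those of nifD and nifK were 1668-fold and 1308-fold lower. The assembly genes nifU, nifS and nifV were 1160-fold, 1068-fold and 834-fold lower, nifE and nifN 510-fold and 385-fold, and the ferredoxin gene fdxB 367-fold. The level of nifB dropped 7.20-fold, to 1281 ± 144, and that of nifL 3.33-fold, from 4349 ± 413 to 1306 ± 122 (SD, n = 2 each; log2 -1.73 ± 0.095 SE, limma Benjamini-Hochberg adjusted p = 2.55e-07). The list was called lower by limma camera (Benjamini-Hochberg adjusted p = 7.75e-25, or 5.06e-23 without the deleted gene; adjusted p = 0.249 with an estimated correlation), and 12 of 12 genes fell over all genes, adjusted over the list alone and as deposited.

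The genes modA, modB, modC, rsxA, rsxC, ahpC and ahpF fell here too. The molybdate genes modA, modB and modC were 140-fold, 166-fold and 166-fold lower than in the parent, rsxA and rsxC 131-fold and 79.0-fold, and ahpC and ahpF 6.99-fold and 5.35-fold. Other rsx genes rose, rsxD with a log2 change of 0.49 and rsxG of 0.32 (limma Benjamini-Hochberg adjusted p = 0.0131 and 0.0286), but both missed the threshold without parent replicate 1 (0.0596 and 0.139) or nifA deletion replicate 1 (0.0768 and 0.191), and rsxG also without parent replicate 2 (0.0857). Unlike rsxD and rsxG, rsxA and rsxC are sums over several loci, so their falls may lie at loci other than those of rsxD and rsxG. For modA the larger of the summed rows was at 30.8 and 32.2 deposited FPKM in the nifA deletion and the smaller at 9.76 and 10.6. These rows are again ranked by size in each library and need not be the same loci as in the parent. The molybdenum and iron supply list had 3 higher and 6 lower of 19, over all genes and adjusted over the list alone, with a median log2 change of 0.02 and a mean of -1.10. It was not called (limma camera, Benjamini-Hochberg adjusted p = 0.186), but was called lower on FPKM as deposited (0.0163), although 15 members were then called higher and 3 lower, with a median of 0.52. The Rnf and flavodoxin list had 3 higher and 2 lower of 10, likewise adjusted over the list alone (adjusted p = 0.606), with a median of 0.08, a mean of -1.17 and a test direction of lower. As deposited 8 of its members were higher and 2 lower.

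The nitrogen assimilation and scavenging list was not called. It had 10 higher and 7 lower of 21 tested (12 and 8 adjusted over the list alone; limma camera, Benjamini-Hochberg adjusted p = 0.48), and 14 and 1 as deposited. Among its members the urea transporter gene urtC was 1.54-fold higher and the urease accessory gene ureG stood at 257 ± 52.3 against 122 ± 3.08 (SD, n = 2 each; limma Benjamini-Hochberg adjusted p = 0.00515). The regulator genes glnL and glnG were at 63.1% and 55.6% of the parent (91.5% and 80.7% as deposited, where glnL no longer passed). Glutamine synthetase, glnA, was at 4977 ± 596 (SD, n = 2) against 6709 ± 527, a log2 change of -0.43 (limma Benjamini-Hochberg adjusted p = 0.00888) that turned to 0.10 as deposited and missed the threshold without parent replicate 1 (0.0565) or nifA deletion replicate 1 (0.0691). At 59.8 ± 0.277, glnB did not pass the test after rescaling (log2 -0.10, limma Benjamini-Hochberg adjusted p = 0.414), and as deposited it was called higher (log2 0.42, adjusted p = 0.00283).

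Many ribosomal protein genes, all taken by a pattern of symbols written after the data were seen, rose by small amounts, rpmE 1.99-fold, rpmB 1.75-fold, rpsL 1.68-fold and rpsJ 1.53-fold. Of 54 members 30 rose and 0 fell (31 and 0 adjusted over the list alone), with a median log2 change of 0.25. As deposited all 54 rose, but so did 970 of all 1198 genes tested. The list was called higher by limma camera (Benjamini-Hochberg adjusted p = 2.66e-10; adjusted p = 0.361 with an estimated correlation). The gene with the largest rise was tnaA, for tryptophanase, from 31.0 ± 3.35 to 101 ± 5.22 (SD, n = 2 each), 3.24-fold (limma Benjamini-Hochberg adjusted p = 2.6e-06). Also among the 10 called genes with the largest rise were ureG and rpmE, named above, suhB (2.21-fold), rph and rnpA, for RNA processing enzymes (2.26-fold and 2.08-fold), rlmH, an rRNA methyltransferase gene (2.15-fold), the export gene fliR of the flagellum (2.15-fold), xseA, an exonuclease gene (1.97-fold) and pyrD, of pyrimidine synthesis (1.88-fold).

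Some biosynthetic and anaerobic genes fell. The arginine genes argB, argC and argH were 3.98-fold, 2.71-fold and 2.04-fold lower and asnB, for asparagine synthetase, 1.98-fold lower. The amino acid list had 2 higher and 16 lower of 58, and 0 and 15 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0269; adjusted p = 0.361 with an estimated correlation), but as deposited it turned to 47 higher and 4 lower and was not called (0.491). Fumarate reductase genes frdC and frdA were 2.21-fold and 2.18-fold lower. Their anaerobic list had 0 higher and 8 lower of 18, likewise adjusted over the list alone (adjusted p = 0.0278; adjusted p = 0.373 with an estimated correlation). As deposited its counts turned to 9 higher and 2 lower, while camera, which compares a list with other genes, still called it (adjusted p = 0.0163). Its call was lost without parent replicate 1 (limma camera, Benjamini-Hochberg adjusted p = 0.0506).

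The medians of the phage shock, heat shock and carbon storage lists lay below 0 after rescaling and above 0 as deposited. The phage shock genes pspA and pspG were 1.90-fold and 1.75-fold lower, and 5 of 9 members of the list fell and 0 rose, likewise adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.0377; adjusted p = 0.361 with an estimated correlation). As deposited the counts turned to 4 higher and 3 lower, and camera still called the list (adjusted p = 0.0163). The call of the phage shock list was lost without parent replicate 1 or nifA deletion replicate 2. Heat shock and chaperone genes had 0 higher and 10 lower of 15, likewise adjusted over the list alone (adjusted p = 0.00471; adjusted p = 0.373 with an estimated correlation), but 6 higher and 0 lower as deposited, where the list was not called (0.0748). The carbon storage list had 0 higher and 2 lower of 6, and 0 and 5 adjusted over the list alone (adjusted p = 0.0377; adjusted p = 0.373 with an estimated correlation), but 4 higher and 0 lower as deposited (0.317), and was not called without parent replicate 1 (0.0654) or nifA deletion replicate 2 (0.121).

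Of 11 transporter genes 6 rose and 0 fell, likewise adjusted over the list alone, with gltS 1.51-fold and putP 1.46-fold higher, and all 11 rose as deposited. The list was called higher by limma camera (Benjamini-Hochberg adjusted p = 0.0285; adjusted p = 0.589 with an estimated correlation), but not as deposited (0.234), nor without parent replicate 1 (0.0518) or nifA deletion replicate 2 (0.0807). Flagellar genes had 7 higher and 10 lower of 31 (8 and 10 adjusted over the list alone), with flgC 1.70-fold lower, and 20 higher and 3 lower as deposited (adjusted p = 0.48). Oxidative stress genes had 1 higher and 2 lower of 9 (0.333), and quorum sensing genes 1 higher and 0 lower of 5 (0.352), both likewise adjusted over the list alone. Stringent response genes had 1 higher and 1 lower of 10 (0.596), and 1 and 3 adjusted over the list alone. Of 7 ATP synthase genes 2 were higher and 0 lower, likewise adjusted over the list alone (0.0586), and the list was called without ntrBC deletion replicate 1 (0.041) or 2 (0.0389). As deposited the oxidative stress and stringent response lists turned to 7 higher and 2 lower, and 9 higher and 0 lower, and all 5 quorum sensing and all 7 ATP synthase genes were higher.

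In all, limma with Benjamini-Hochberg adjustment called 442 of 1197 genes in the nifA deletion, 221 higher and 221 lower, with 7 higher and 27 lower by a log2 of at least 1. The count was 234 without parent replicate 1, 288 without parent replicate 2 and 289 without nifA deletion replicate 2. On FPKM as deposited 970 were higher and 40 lower. Under both scalings 221 were called higher and 40 lower, with 41 called in opposite directions, and 7 were higher and 24 lower by a log2 of at least 1 under both. Here too the shift favours higher calls, so the agreement among higher genes was largely fixed in advance.

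**Figure D3:**
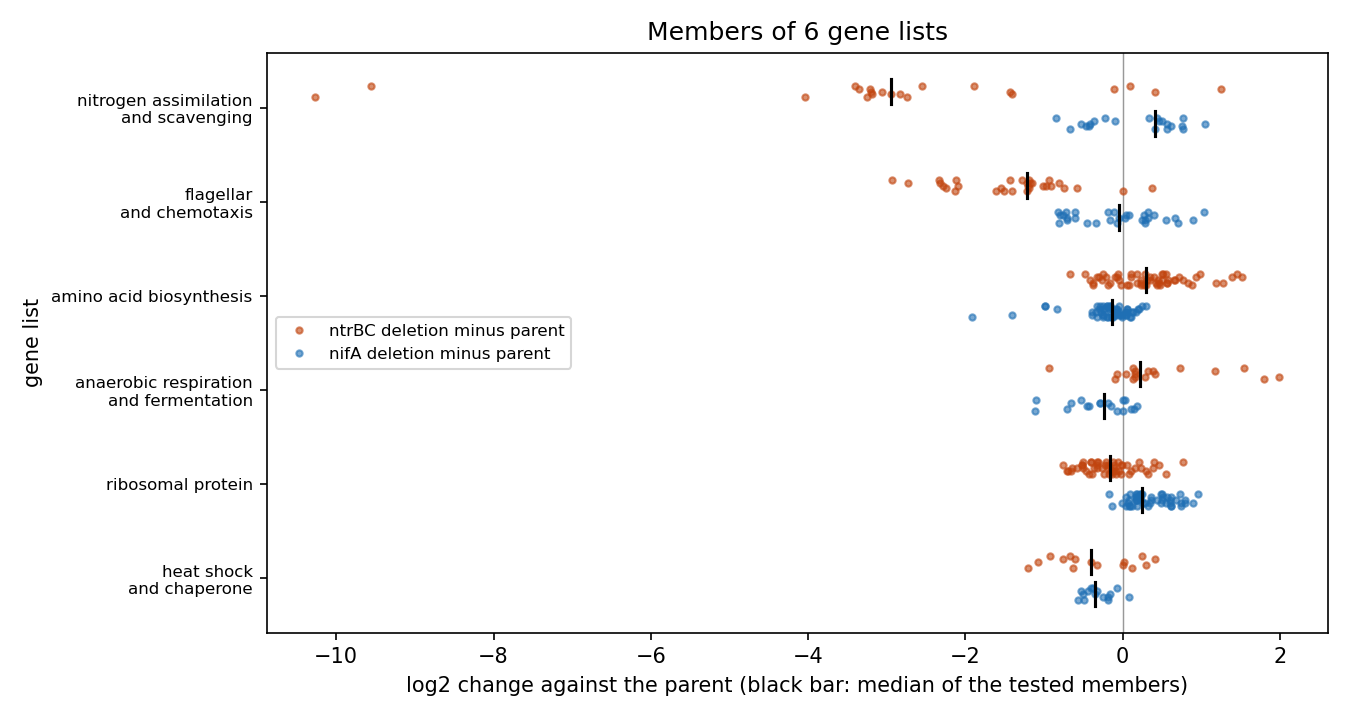
Log2 change against the parent of the tested members of 6 gene lists, on log2(rescaled FPKM + 1), in the ntrBC deletion (orange) and the nifA deletion (blue), with 1 dot per gene and a black bar at the median. Nitrogen assimilation and flagellar medians lie at -2.95 and -1.21 in the ntrBC deletion, and on FPKM as deposited the medians turn positive for ribosomal (0.79) and heat shock genes (0.51) in the ntrBC deletion and for flagellar (0.49), amino acid (0.39), anaerobic (0.29) and heat shock genes (0.18) in the nifA deletion.

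Both deletions were compared directly to find where they differ. The ethanolamine genes eutC and eat were 10560-fold and 1821-fold higher in the nifA than in the ntrBC deletion. The xanthine dehydrogenase genes xdhA, xdhB and xdhC were 630-fold, 382-fold and 370-fold higher and uraH, of urate breakdown, 399.6-fold higher. Of the nif genes, nifL was 526-fold higher, nifB 244-fold and nifA itself 28.9-fold, while nifH was 7.30-fold, nifD 3.60-fold and nifK 3.45-fold higher. The levels of nifH, nifD and nifK were 14.6, 16.5 and 13.1 in the nifA deletion and 2.00, 4.58 and 3.81 in the ntrBC deletion. In the parent they were 21583, 27500 and 17192, so these folds compare small remainders. The nifA level in the nifA deletion, 92.9, is a remainder at the deleted gene. All 12 nitrogenase genes were higher, over all genes, adjusted over the list alone and as deposited (limma camera, Benjamini-Hochberg adjusted p = 1.47e-07, or 7.89e-07 without the deleted nifA; adjusted p = 0.337 with an estimated correlation). In glnA the difference was 5.75-fold (log2 2.52 ± 0.10 SE, limma Benjamini-Hochberg adjusted p = 7.98e-09). After rescaling glnB did not differ past the threshold (log2 0.00, limma Benjamini-Hochberg adjusted p = 0.977), but as deposited it was called lower (log2 -0.41, adjusted p = 0.0037).

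Most tested nitrogen assimilation and flagellar genes were higher in the nifA than in the ntrBC deletion. In the nitrogen list 17 of 21 were higher and 3 lower, likewise adjusted over the list alone and with 17 and 4 as deposited, among them nirD (22.8-fold) and aspA (15.9-fold). The 17 include glnL and glnG, which the ntrBC deletion strain lacks. The nitrogen list was called higher by limma camera (Benjamini-Hochberg adjusted p = 2.26e-07, or 8.58e-06 without the deleted genes; adjusted p = 0.337 with an estimated correlation). In the flagellar list 28 of 31 were higher and 1 lower, likewise adjusted over the list alone and with 26 and 4 as deposited, among them fliD (6.21-fold) and flgK (5.52-fold), with an adjusted p of 7.1e-09 (adjusted p = 0.337 with an estimated correlation). Ribosomal protein genes had 36 higher and 3 lower of 54, and 37 and 4 adjusted over the list alone, with rpsT 3.01-fold higher (adjusted p = 2.7e-05; adjusted p = 0.337 with an estimated correlation). As deposited the ribosomal counts went to 18 higher and 16 lower, and camera still called the list (adjusted p = 0.00384).

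Lower in the nifA than in the ntrBC deletion were punC (181-fold), frdC (7.80-fold), frdD (7.05-fold), frdA (6.44-fold), argC (6.93-fold), argH (5.68-fold), argA (5.08-fold), argB (4.25-fold), asnB (3.89-fold) and hisC (3.54-fold). The amino acid list had 8 higher and 38 lower of 58, and 9 and 38 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 5.92e-07; adjusted p = 0.25 with an estimated correlation), with 0 and 49 as deposited. The anaerobic list had 1 higher and 11 lower of 18, likewise adjusted over the list alone (adjusted p = 0.000393; adjusted p = 0.337 with an estimated correlation), with 1 and 17 as deposited.

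The other lists were not called in this comparison by limma camera. Benjamini-Hochberg adjusted p was 0.82 for molybdenum and iron supply (9 higher and 7 lower of 19), 0.544 for Rnf and flavodoxin (4 and 1 of 10), 0.98 for ATP synthase (1 and 0 of 7), 0.98 for the stringent response (3 and 2 of 10), 0.653 for quorum sensing (1 and 2 of 5), 0.82 for phage shock (1 and 1 of 9), 0.907 for heat shock (5 and 4 of 15), 0.803 for oxidative stress (4 and 1 of 9), 0.31 for carbon storage (4 and 1 of 6) and 0.377 for transporters (2 and 6 of 11). Adjusted over the list alone the counts were the same, except for ATP synthase (0 and 0) and carbon storage (5 and 1). On FPKM as deposited, the counts of higher and lower genes were 7 and 8 for molybdenum and iron supply, 2 and 4 for Rnf and flavodoxin, 0 and 6 for ATP synthase, 0 and 6 for the stringent response, 0 and 4 for quorum sensing, 0 and 7 for phage shock, 1 and 9 for heat shock, 0 and 3 for oxidative stress, 2 and 1 for carbon storage and 1 and 8 for transporters. Transporters had a median log2 difference of -0.35 and a mean of 0.04 with a test direction of lower, and the stringent response and heat shock lists had medians and means above 0 with a test direction of lower. In total 740 genes were called, 410 higher and 330 lower in the nifA deletion, with 137 higher and 29 lower by a log2 of at least 1. As deposited 197 were higher and 701 lower. Under both scalings 197 were called higher and 330 lower and 4 in opposite directions, with 92 higher and 29 lower by a log2 of at least 1 under both. In this comparison the deposited values favour lower calls, so the agreement among lower genes was largely fixed in advance.

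Of the 129 genes lower in the ntrBC deletion by a log2 of at least 1, 23 were also lower by that much in the nifA deletion. The 129 include the deleted glnL and glnG, and the 23 include the deleted nifA. In 13 of the 23, the 12 nitrogenase genes (nifA among them) and fdxB, the level was higher in the nifA than in the ntrBC deletion by a log2 of at least 1. The other 10 were modA, modB, modC, rsxA, rsxC, ahpC, ahpF, nqrM, hcp and pulA. Of these, nqrM, hcp and pulA are outside the rule and named because the group was counted after its values were seen. The values of modA, modB, modC, rsxA, rsxC and nqrM sum rows of several loci. A second locus could set their remaining level in both deletions, so their separation from the 13 may come from the summing. A further 71 of the 129 were not called lower in the nifA deletion and were higher there than in the ntrBC deletion by a log2 of at least 1, and eutC, eat, nirD, aspA and putP are among them. All these groups rest on rescaled values. As deposited too, 72 of the 129 were lower by a log2 of at least 1. In the direct comparison 92 of 137 genes were higher by that much under both scalings.

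Over all 1197 genes, 106 were called lower in both deletions, where independent lists of the observed sizes give 60. In 100 simulations of strains with no change at all against the same parent libraries at most 1 gene was, a value that leaves out the effects, as that of independent lists leaves out the shared parent. Called higher in both were 45 (52.4 for independent lists), lower in the ntrBC and higher in the nifA deletion 72 (60), and higher in the ntrBC and lower in the nifA deletion 40 (52.4). As deposited 28 were called lower in both. Both comparisons share the parent libraries, which are too few to be split, so part of the excess may come from them, and it is not read as a shared effect.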

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

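The comparison of both effects, with a log2 change of at least 1 in each, was planned, and every test of an explanation below was chosen after the result had been seen.

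In 8 genes the deletions moved transcript levels in opposite directions, each by a log2 of at least 1 from the parent, with a difference past the threshold of limma with Benjamini-Hochberg adjustment. The signs were opposite in all 8 on FPKM as deposited, but only ureG and tnaA then had a log2 change of at least 1 in both deletions. The smaller of both changes was then -0.11 for rnpA, -0.18 for suhB and -0.60 for fliR in the ntrBC deletion, and -0.58 for frdA, -0.60 for frdC and -0.88 for argC in the nifA deletion. Lower in the ntrBC and higher in the nifA deletion were tnaA, for tryptophanase (log2 -4.03 and 1.67, difference 5.69, adjusted p = 1.91e-11), ureG, a urease accessory gene (-3.21 and 1.05, difference 4.26, adjusted p = 5.97e-08), fliR, of flagellar export (-1.43 and 1.03, difference 2.47, adjusted p = 2.02e-07), suhB (-1.10 and 1.13, difference 2.24, adjusted p = 2.02e-05) and rnpA, of ribonuclease P (-1.03 and 1.06, difference 2.1, adjusted p = 1.4e-05). Higher in the ntrBC and lower in the nifA deletion were frdC (1.79 and -1.12, difference -2.91, adjusted p = 5.22e-09) and frdA (1.54 and -1.10, difference -2.65, adjusted p = 7.99e-09), of fumarate reductase, and argC, of arginine synthesis (1.28 and -1.41, difference -2.69, adjusted p = 6.85e-06). The libraries of a strain lay far apart in some of these. In the ntrBC deletion, argC was at 213 and 425 and suhB at 12.2 and 24.1, against 139 and 110, and 33.8 and 43.0, in the parent.

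The median FPKM as deposited was higher in both deletions than in the parent, and the rescaling removes this shift, a log2 of 0.96 in the ntrBC and 0.54 in the nifA deletion by the scale factors. Loss of abundant transcripts could raise all other values: the 129 genes that fell by a log2 of at least 1 in the ntrBC deletion went from 19.1% to 1.23% of fragments, which gives a shift of 0.287, and the 27 genes of the nifA deletion went from 12.8% to 0.454%, which gives 0.191. A shift of the observed size needs a lost share of 48.6% and 31.1%, and the 49.1% of parent fragments outside the listed genes is not analysed here, so this stays open for both deletions, although the listed share fell from 51.2% and 50.5% in the parent to 46.4% and 45.8% in the nifA deletion, where unlisted transcripts as a whole gained share by less than the shift would give. A larger share of messenger against stable RNA predicts that ssrA and rnpB do not rise with the median gene of the ntrBC deletion, and as deposited they rose by 0.394 and 0.0749 on the log2 scale, between no rise and the full shift, so this too cannot be told apart, and in the nifA deletion they rose by 0.159 and 0.254. A true rise of most messenger RNAs in the deletions was not tested and stays open.

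The level of punC rose by a log2 of 6.27 in the ntrBC deletion. A single library that stands apart is argued against, since the lower of both libraries was 89.4 times the highest of the other strains. Transcription running in from the neighbour punR might reach punC. The level of punR, which is outside the rule, differed by only 0.539 on the log2 scale. It was at 1.74 and 1.77 in the ntrBC deletion against 0.828 and 0.968 in the parent. In the same ntrBC deletion libraries punC was at 113 and 220, so a transcript that covers both genes alike is argued against. Transcription that starts within punR was not tested. The next genes outward, glmU and ilvA, also outside the rule, had log2 changes of -0.09 and -0.19. A second change in the genome of the ntrBC deletion strain, and control of punC by NtrC, were not tested and stay open.

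In the nifA deletion nifL and nifB, the neighbours of nifA, fell by less than the other nitrogenase genes named. A transcript cut short at the deleted gene would spare whichever neighbour precedes it, but the smaller of both falls was still -1.73 (SE 0.095), for nifL, against -2.85 for nifB, so it is argued against as the whole cause. The rescaling is argued against as well, since on FPKM as deposited nifL changed by -1.20 and nifB by -2.31. An action of NifA on nifL and nifB, a hypothesis, was not tested and stays open, and so does an effect of the deletion on the stability of the neighbouring transcripts.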

How the results depend on the processing

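The fits without repeated identifiers, the lists without the deleted genes and the lists of symbols fixed before alone were chosen after the data were seen, and all other alternatives before. On FPKM as deposited 1128 genes were called in the ntrBC deletion and 1010 in the nifA deletion (609 and 442 after rescaling), because a median shift of 0.92 and 0.52 on the log2 scale is then counted as change. The genes called lower in both fell to 28 (106), the lists called in the nifA deletion to 5 (8), and nifA in its own deletion came to 4.09% of the parent (2.82%). A size threshold of log2 1 leaves 146, 34 and 166 genes in the ntrBC, the nifA and the direct comparison. With an estimated correlation camera called 0, 0 and 0 lists (6, 8 and 6), and fry, which does not compare a list with other genes, 13, 10 and 9. Other pseudocounts, filters, priors and fits of 2 strains stayed within 1.5 times each count of genes, as did trimmed-mean rescaling and rRNA and tRNA genes kept. Symbols fixed before alone left no test of the ribosomal protein and flagellar lists and 5, 7 and 4 lists called. Without repeated identifiers 552, 410 and 682 genes were called.

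With 1 library left out, its partner is assumed to vary like the other strains. The counts of called genes then ranged over 456 to 594, 234 to 472 and 630 to 735, the lists called over 6 to 7, 4 to 9 and 6 to 6, and the genes lower in both over 81 to 107. In the nifA deletion the counts were 234 without parent replicate 1, 288 without parent replicate 2 and 289 without nifA deletion replicate 2, and its lists 4 without parent replicate 1 and 5 without nifA deletion replicate 2. The cause was not tested. Replicate numbers as a block gave 609, 446 and 741 genes and 6, 8 and 6 lists. Deviations of libraries with the same number had correlations across genes of 0.0285, -0.0916 and 0.0507, so little shared deviation was seen. This does not show whether samples with the same number were handled together.

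The named genes were refitted under 13 of the alternatives, which leave out the other priors, fits of 2 strains, rRNA and tRNA genes kept and repeated identifiers. Counted once per gene, comparison and alternative, 2636 log2 changes kept direction and side of the threshold, 56 lost the threshold and 26 turned, all 26 on FPKM as deposited, where the added shift accounts for the sign. In the ntrBC deletion these were glnB (0.84), rsxG (0.52), rpmB (0.36), rpsU (0.18), rpoS (0.57), spoT (0.47), hpf (0.51), pspA (0.13), pspB (0.34), pspC (0.49), hslV (0.026), hslU (0.19), soxR (0.36) and glgB (0.13). In the nifA deletion they were glnB (0.42), glnA (0.10), iscR (0.20), groL (0.039), dnaK (0.033), hslU (0.087), pflB (0.0039) and malQ (0.10), and in the direct comparison glnB (-0.41), luxQ (-0.10), sodB (-0.085) and soxR (-0.0385). TPM, coverage and tests of read counts were not run, since the files used here hold FPKM alone. Depth is unknown, so what it limits cannot be stated.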

Other observations

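The lists in this part were put together after the data were seen, so only counts of called genes are given for them and no p of a list. Except for xdhA, xdhB and xdhC, the single genes named in this part are outside the rule. They were chosen after the data were seen. In the ntrBC deletion the xanthine dehydrogenase genes xdhA, xdhB and xdhC went from 2737, 3085 and 1849 in the parent to 3.28, 5.64 and 3.65, guaD, for guanine deaminase, from 1627 to 16.3, and putA, of proline breakdown, from 336 to 23.7 (means of rescaled FPKM, n = 2, with rows of several loci summed for putA). In the nifA deletion guaD stood at 1619 and putA at 385, and neither passed the test against the parent (limma Benjamini-Hochberg adjusted p = 0.946 and 0.108). There xdhA, xdhB and xdhC stood at 2068, 2152 and 1351, and after rescaling they were called lower than in the parent. Of 21 tested genes for the breakdown of purines, ethanolamine and amino acids, 14 fell and 1 rose in the ntrBC deletion, with 14 lower and 7 higher as deposited. Among the members not called was hutI, of histidine breakdown, at 13.3 in the parent and 11.2 in the ntrBC deletion (limma Benjamini-Hochberg adjusted p = 0.155). In the nifA deletion 3 of the 21 rose and 9 fell, turning to 10 higher and 0 lower as deposited. Compared directly, 14 were higher and 4 lower in the nifA than in the ntrBC deletion, and 14 and 7 as deposited.

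In the ntrBC deletion the lactate dehydrogenase genes dld and lldD went from 755 to 39.3 and from 159 to 11.2, the fatty acid oxidation genes fadB and fadA were 7.46-fold and 7.06-fold lower, and sdhA, of succinate dehydrogenase, and aceE, of pyruvate dehydrogenase, 2.77-fold and 2.39-fold lower. Of 28 tested genes of aerobic carbon oxidation 25 fell and 0 rose, and on FPKM as deposited 18 fell and 7 rose. In the nifA deletion 2 rose and 10 fell, turning to 17 higher and 1 lower as deposited. Compared directly, 25 were higher and 2 lower in the nifA than in the ntrBC deletion, and 20 and 3 as deposited.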
